A study of Homo sapiens with 4 samples.

How the data were processed

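Libraries were made from total RNA with a TruSeq RNA kit, which selects polyadenylated RNA and does not mark the strand. Each of the 4 libraries came from MCF7 cells kept in medium of senescent fibroblasts, 2 with LCN2 intact (LCN2+/+) and 2 with LCN2 knocked out (LCN2-/-). A table of raw counts per gene symbol was deposited, with whole numbers and a different total in each library, and a second table was deposited of normalized values, a signal that the authors made by dividing each raw count by 1 size factor per library. The size factors were 0.998 and 0.962 for LCN2+/+ replicates 1 and 2 and 1.07 and 0.990 for LCN2-/- replicates 1 and 2, as computed from the ratio of both tables. DESeq2 is named in the submitters' processing notes without a version or a role. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here. Libraries were matched to genotypes by the sample codes in the labels, and 0 columns were left unused.

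The tables held 59611 gene symbols. EEF1A1, the symbol with the most counts, took between 0.935% and 1.04% of a library. The mitochondrially encoded genes had no entries, so that list had 0 tested members. For positions, 54002 symbols were placed on GENCODE release 29 (GRCh38), 954 of them through a newer symbol, and 17667 of the tested genes had a place. The spread between the libraries of a genotype was above counting error alone. Its mean chi-square per gene was 29.4 for LCN2+/+ over 13969 genes and 31.8 for LCN2-/- over 13938 genes with at least 100 reads over both libraries, where counting error alone gives about 1, and its median was 4.13 and 3.61.

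Raw counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 18180, libraries were scaled by TMM, and LCN2-/- was compared with LCN2+/+ by the robust quasi-likelihood F-test with genotype as the only term. P-values were adjusted by Benjamini-Hochberg over all tested genes, and a gene was called changed at an adjusted p under 0.05. With 2 libraries per genotype the fit had 2 residual degrees of freedom, a median of 3.82 prior degrees of freedom and a common biological coefficient of variation of 0.110. Standard errors (SE) are the absolute log2 fold change over the square root of the F statistic. CPM are counts scaled to a common library total by TMM, given as the mean ± SD of both libraries of a genotype. The principal components of log2 CPM put 73.1% of the variance on the component that parted the genotypes, and 16.9% on one that parted LCN2+/+ replicate 1 from 2 and, less far, LCN2-/- replicate 1 from 2.

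The tests, the gene lists, the rule for named genes and 14 of the alternatives given at the end were chosen before the data were examined. The rule named LCN2, the 12 largest rises and the 12 largest falls among changed genes with a symbol and a mean of at least 5 CPM, the 4 members of each list with the smallest adjusted p, and list members given as not past the test. Other genes were picked out after their values were seen, and this holds for every gene named outside that rule. There were 21 fixed lists, and 20 of them had tested members. A further 8 lists were added after the values were seen. They hold complement genes, S100 genes, mucins, actin-binding and contractile genes, T lymphocyte markers, hepatocyte markers and held-out markers of both of these cell types. Each list was tested by camera in limma 3.58.1 against all other genes on log2 CPM (prior count 2), with a preset correlation of 0.01 and with an estimated correlation. It was also tested by fry, which asks whether members move on balance to 1 side, and both were adjusted by Benjamini-Hochberg over the 20 fixed or the 8 added lists. Of the fixed lists 3 passed camera with the preset correlation (hypoxia and glycolysis, IL6-STAT3 and acute phase, cholesterol synthesis), 0 with an estimated correlation, and 0 by fry, while fry for change in either direction passed 16. With an estimated correlation camera rests on the 2 residual degrees of freedom and has little power. The iron handling list went from a camera adjusted p of 0.101 to 0.904 although its estimated correlation was only -0.04. A high value from that test therefore does not show that a list stayed unmoved.

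The local median of a gene is the median log2 fold change of the 40 nearest other tested genes with a mean of at least 1 CPM on its chromosome. At each position of the genome the median of the 30 tested genes on one side was compared with that of the 30 on the other side. This scan and the counts, medians and step along chromosome 9 used only tested genes with a mean of at least 1 CPM, 13571 over the genome.

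The procedure was tested on simulated counts in which known genes had been changed. It recovered 38 of 62 genes changed 1.5-fold, 61 of 70 changed 2-fold and 68 of 68 changed 4-fold, and called 7 of 17555 unchanged genes. Far fewer genes were changed there than the 4611 of 18180 called in the data. Each simulated gene took the spread typical of its level, and no shift was shared by like-numbered libraries. These rates of recovery and false calls therefore need not hold in the data. A list of 25 members all raised 1.5-fold was called by camera with the preset correlation, and 0 of 20 unchanged lists were. Each simulated gene was drawn on its own, so this does not cover false calls of lists whose members vary together. In the data the estimated correlation within a list reached 0.68 for cell cycle genes and 0.99 for T lymphocyte markers.

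The alternatives were edgeR with RLE or upper quartile factors, DESeq2 1.42.0 with its Wald test, limma-voom, no low-count filter, a mean of at least 5 CPM, the replicate number as a block, each library left out in turn, and limma-trend on the log2 of the deposited normalized values with a pseudocount of 1 or 0.1 and with a pseudocount of 1 without a filter. Where 1 library was left out, the lone library of its genotype was assumed to vary like the other genotype. An alternative added after the data were examined took each gene's fold change relative to its local median (local centring). Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternative splicing, sequence variants and the edit itself were left out, since counts per gene do not hold them.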

Results

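Messenger RNA was profiled in MCF7, an established human breast cancer line that carries the estrogen receptor, with the LCN2 gene intact (LCN2+/+) or knocked out (LCN2-/-). LCN2 encodes lipocalin 2, a secreted protein that binds iron-carrying siderophores. The cells of both genotypes had been kept in medium taken from senescent fibroblasts, which secrete many cytokines and growth factors, and no library from cells in other medium was analysed here. There were 2 libraries per genotype. The LCN2+/+ libraries held 56689183 and 53599294 counts over genes, and the LCN2-/- libraries held 63489379 and 57321497. The labels give both libraries of a genotype 1 shared code, so the knockout and the cell line that carries it cannot be separated, and nothing states that the libraries of a genotype came from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical. Like-numbered libraries also share a code across the genotypes, and what that code marks is not stated. Part of the spread went with the replicate number in both genotypes. Deviations of like-numbered libraries correlated at 0.583 among genes with a mean of at least 5 CPM. The main test, without a replicate block, leaves this shared part in its error. The comparison asked which transcripts differ between tumour cells with and without LCN2 in the medium of senescent fibroblasts.

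LCN2 itself was checked in every library before other genes. It fell by 3.32 on the log2 scale (SE 0.16, n = 2 per genotype), to 9.98% of its LCN2+/+ level (95% limits 7.61% and 13.1%). LCN2 stood at 452 and 524 CPM (counts scaled to a common library total, by TMM) in LCN2+/+ replicates 1 and 2, and at 39.7 and 53.9 CPM in LCN2-/- replicates 1 and 2. Both libraries labelled LCN2-/- thus lay below both labelled LCN2+/+. The adjusted p for LCN2 was 0.000989 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The gene lies on chromosome 9 from 128149071 to 128153455 on the plus strand (GRCh38, GENCODE release 29), and GENCODE lists it as protein-coding. Counts per gene do not show which exon was edited or whether the remaining LCN2 transcripts were intact.

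The largest changes in the LCN2-/- libraries included rises of WLS, C3 and STC1 and falls of the actin-binding PLS3, TAGLN and LCP1, while the actin-severing SCIN rose. WLS, which carries Wnt proteins to the cell surface, rose by 4.21 on the log2 scale (SE 0.13, n = 2 per genotype), from 1.37 ± 0.196 to 24.3 ± 0.539 CPM (mean ± SD). C3, the central component of complement, rose by 2.25 (SE 0.09), from 225 ± 1.58 to 1032 ± 109 CPM, and STC1, a secreted glycoprotein, rose by 2.28 (SE 0.11). PLS3, an actin-bundling plastin, fell by 6.30 (SE 0.12), from 217 ± 9.83 to 2.64 ± 0.413 CPM. CT83, which lies near PLS3 on chromosome X, fell as well (below). A further plastin, LCP1, fell by 3.12 (SE 0.07), and the actin-binding TAGLN fell by 4.35 (SE 0.25).

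In all, 4611 of 18180 tested genes differed, 2214 of them higher and 2397 lower in LCN2-/- cells, at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 480 were at least 2-fold higher and 686 at least 2-fold lower. Where a mean of at least 5 CPM was required, only 144 were at least 2-fold higher and 203 at least 2-fold lower. Many calls followed stretches of chromosomes. Among genes with a mean of at least 1 CPM, 28 rose and 328 fell of 903 on chromosome 2. From 10.5 to 31.9 Mb on chromosome 16, 2 rose and 122 fell of 183, and up to 20.2 Mb on chromosome 1, 106 rose and 1 fell of 184. Both stretches were chosen from these same fold changes, as runs of genes with a local median beyond 0.35. Their 1-sided counts therefore describe the stretches and are no separate support. Fold changes of adjacent genes correlated at 0.264, against at most 0.029 in 10000 shuffles. The count therefore cannot be read as a response to LCN2 alone. The other largest rises among genes with a mean of at least 5 CPM were those of PCP4 (a calmodulin-binding peptide, log2 fold change 3.32, SE 0.17), UGT1A7 (2.97, SE 0.33), the ubiquitin ligase RNF145 (2.38, SE 0.07), the actin-severing SCIN (2.23, SE 0.20) and the estrogen-induced matricellular gene CCN5 (2.17, SE 0.34). The collagen chain COL5A2 (2.15, SE 0.31), the nicotinic acid receptor HCAR2 (2.05, SE 0.21), the transcription factor MAF (1.95, SE 0.13) and the kinase HIPK2 (1.91, SE 0.12) completed the 12.

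The cancer/testis antigen gene CT83 had the largest fall, by 7.40 on the log2 scale (SE 0.27), from 10.6 ± 1.58 to 0.0577 ± 0.00755 CPM. On chromosome X, CT83 starts at 116461682 and PLS3 at 115561174, and both had a local median of 0.002. A median of 40 genes can miss a change confined to a few genes. Whether both falls share a local cause was not tested. The long non-coding RNA LINC00665 had a log2 fold change of -6.57 (SE 0.14), the mitochondrial calcium-binding EFHD1 of -4.74 (SE 0.23) and FKBP10, a peptidyl-prolyl isomerase that acts on collagen, of -4.48 (SE 0.10). The remaining genes among the 12 largest falls were TCEAL8 (-3.77, SE 0.13), GDPD3 (-3.28, SE 0.29), TOX3 (-3.07, SE 0.31) and PTGES, the inducible prostaglandin E synthase (-2.99, SE 0.45). LINC00665, GDPD3, PTGES and LCP1 lie in stretches of chromosomes 19, 16, 9 and 13 where the 40 nearest tested genes were lower too. Their local medians were -0.77, -0.64, -0.63 and -0.37 on the log2 scale. UGT1A7 shares exons with its gene family and HCAR2 is almost identical to HCAR3, so their counts are uncertain.

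**Figure D1:**
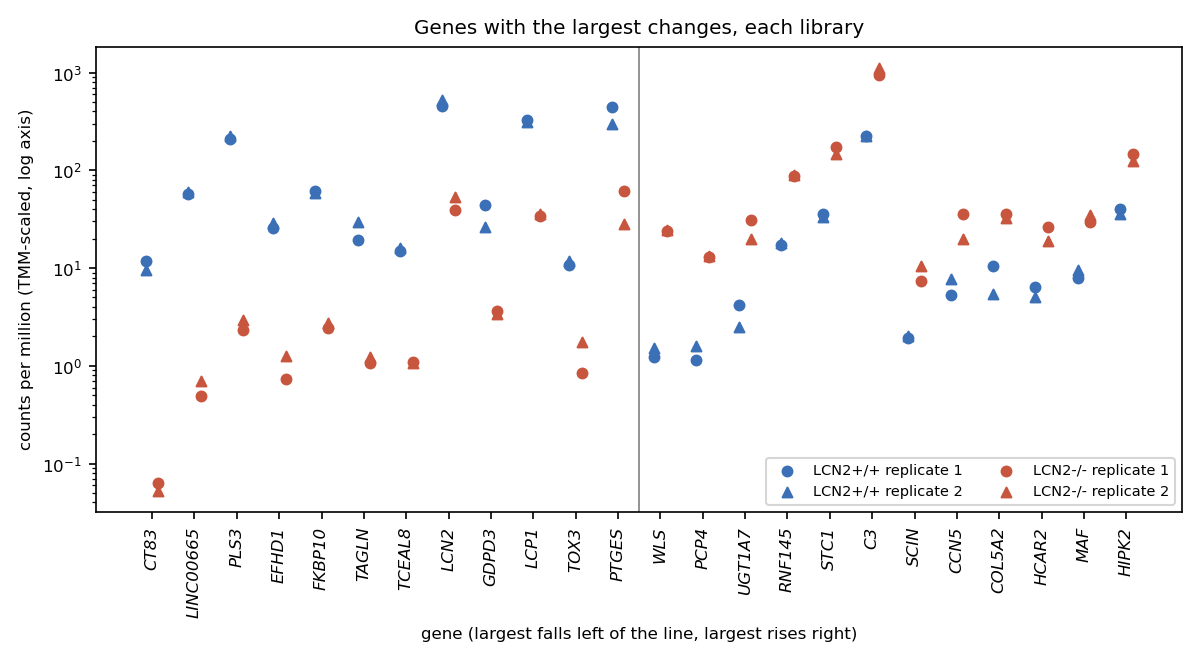
CPM (log axis, TMM-scaled) of the 12 genes with the largest falls and the 12 with the largest rises, with 1 point per library (blue LCN2+/+, red LCN2-/-; circles replicate 1, triangles replicate 2). For every gene shown both LCN2-/- libraries lay on one side of both LCN2+/+ libraries, as for PLS3 at 2.64 against 217 CPM and C3 at 1032 against 225 CPM (means).

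Of the 24 genes with the largest changes, all but CCN5, COL5A2, GDPD3 and PTGES stayed past the test without any 1 library. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, CCN5 had an adjusted p of 0.0836 without LCN2+/+ replicate 1, and COL5A2 (0.299 and 0.276), GDPD3 (0.226 and 0.223) and PTGES (0.0914 and 0.118) missed it without LCN2-/- replicate 1 or 2. PTGES also missed it without LCN2+/+ replicate 1 (adjusted p = 0.0533 by the same edgeR test and Benjamini-Hochberg adjustment). The count of changed genes was 3021 without LCN2+/+ replicate 1, and 2116 of the 4611 genes passed in every one of the 4 fits that left out 1 library. The small counts of the gene lists moved with the libraries too, so the calls of a list that passed in all 4 of these fits are counted below. Each list count is also to be read beside the share over all tested genes, where 2214 of 18180 rose and 2397 fell.

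Of 30 tested genes of hypoxia and glycolysis, 21 rose in the LCN2-/- libraries, 0 fell and 9 did not pass the test, with a median log2 fold change of 0.64. As a group they passed camera with a preset correlation (adjusted p = 1.05e-07) but not with an estimated correlation (adjusted p = 0.904) or by fry (0.109). PFKFB4, which sets the level of a glycolytic activator, rose by 1.37 (SE 0.08), and the glycolytic enzymes ENO2 and LDHA rose by 1.07 (SE 0.08) and 0.66 (SE 0.07). LDHA went from 1347 ± 32.0 to 2036 ± 14.9 CPM (mean ± SD, n = 2). P4HA2, a collagen prolyl hydroxylase, rose by 0.77 (SE 0.08). CA9, a carbonic anhydrase induced by hypoxia, and BNIP3, which acts in mitophagy, rose by 2.07 (SE 0.30) and 1.43 (SE 0.14), and both were picked out after their values were seen. VEGFA, the angiogenic factor, was at -0.40 (SE 0.18) and HK2, a hexokinase, at 0.01 (SE 0.08), neither past the test.

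Camera compared this list with all other genes, at a preset correlation of 0.01, and fry asked whether its members moved on balance 1 way, both adjusted over 20 lists. With an estimated correlation, camera gave all 20 lists an adjusted p between 0.904 and 0.988, so it could not part lists that moved from others. Adjusted over the list alone, 22 members rose and 0 fell. Between 18 and 19 members rose when 1 library was left out, and 16 of the 21 passed in all 4 such fits, while 1 member fell without LCN2+/+ replicate 1. The neighbours of most members did not move with them, since the median of the members' local medians was 0.02. ENO1, the enolase on the short arm of chromosome 1, was an exception, with a log2 fold change of 0.92 (SE 0.10) among neighbours with a median of 0.55.

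**Figure D2:**
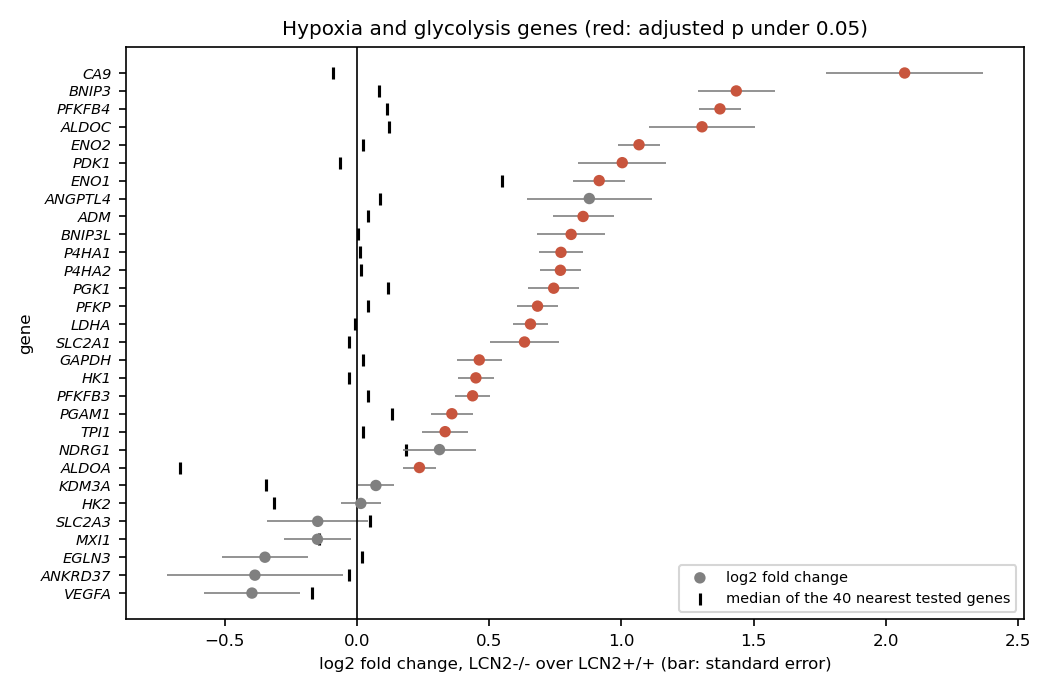
Log2 fold change (LCN2-/- over LCN2+/+, x axis) of each tested member of the hypoxia and glycolysis list, with bars for 1 standard error (n = 2 libraries per genotype), red where the adjusted p was under 0.05 and grey elsewhere. Black ticks give the median of the 40 nearest tested genes, and 21 of the 30 members lie to the right of 0 in red, CA9 farthest at 2.07.

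Among 23 tested acute phase genes and genes of the IL6-STAT3 pathway 10 rose, 0 fell and 13 did not pass. The fibrinogen genes FGA, FGB and FGG of this list, which did not pass, are also markers of hepatocytes, whose transcripts differed between both LCN2+/+ libraries, as ALB at 125 and 26.4 CPM in replicates 1 and 2. IL6R, the interleukin 6 receptor, rose by 1.22 (SE 0.10, n = 2 per genotype), LBP, which binds bacterial lipopolysaccharide, by 1.12 (SE 0.07), LRG1 by 0.91 (SE 0.12) and SOCS3, a feedback inhibitor of cytokine signalling, by 0.77 (SE 0.10). OSMR, the oncostatin M receptor, rose by 1.07 (SE 0.14), from 263 ± 37.0 to 530 ± 63.5 CPM, and was picked out after its value was seen. STAT3 was at 0.18 (SE 0.07) and CEBPB at 0.57 (SE 0.17), not past the test. The camera test gave this list an adjusted p of 0.00657, which became 0.904 with an estimated correlation and 0.0691 without LCN2+/+ replicate 2. Adjusted over the list alone, 11 members rose, and 7 of the 10 passed in all 4 fits with 1 library left out, while 2 members fell without LCN2+/+ replicate 2 and 1 without LCN2-/- replicate 2.

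The NF-kB and inflammatory secretory genes changed in both directions, at about the share of all tested genes. Of 37 tested, 4 rose, 5 fell and 28 did not pass, where 2214 of all 18180 genes rose and 2397 fell. C3 (above), ICAM1, an adhesion molecule (1.26, SE 0.09), the complement factor CFB (1.30, SE 0.10) and the NF-kB regulator BCL3 (0.35, SE 0.09) rose. The neutrophil-attracting chemokine CXCL8 fell by 2.06 (SE 0.09), from 122 ± 8.0 to 28.1 ± 2.86 CPM, and CXCL6, of the same family and picked out after its value was seen, fell by 4.61 (SE 0.39). IL1R1, the interleukin 1 receptor, fell by 1.16 (SE 0.08) among neighbours with a local median of -0.39, and TNFAIP2 and the chemokine CXCL5 fell by 0.91 (SE 0.10) and 0.59 (SE 0.11). NFKBIA was at -0.08 (SE 0.08), SOD2 at 0.22 (SE 0.10) and IL6 at 0.70 (SE 0.52), none past the test. BCL3 missed the test without LCN2+/+ replicate 2 or LCN2-/- replicate 2 (adjusted p = 0.145 and 0.0888, edgeR with Benjamini-Hochberg adjustment) and CXCL5 without LCN2+/+ replicate 1 (0.0574), while 3 of the 4 rises and 4 of the 5 falls passed in all 4 such fits. These 3 genes, BCL3, CXCL5 and TNFAIP2, were picked out after their values were seen. The list had a camera adjusted p of 0.972, and the counts adjusted over the list alone were the same 4 and 5.

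Of 44 interferon-stimulated genes tested, 2 rose, 3 fell and 39 did not pass, a smaller share of changed genes than the 4611 of 18180 over all tested genes. The membrane-bound restriction factor IFITM3 (0.96, SE 0.13) and the GTPase GBP2 (from 20.7 ± 4.99 to 39.7 ± 4.94 CPM) rose, and SAMD9 (-0.94, SE 0.12), OAS1 (-2.92, SE 0.45) and IFITM1 (-0.81, SE 0.20; picked out after its value was seen) fell. IFITM3 and SAMD9 passed in all 4 fits with 1 library left out, but 8 genes of the list rose without LCN2-/- replicate 1 and 9 fell without LCN2-/- replicate 2. GBP2 missed the test without LCN2-/- replicate 2 (adjusted p = 0.0530, edgeR with Benjamini-Hochberg adjustment) and IFITM1 without either LCN2+/+ library (0.0569 and 0.0814). OAS1 missed the test without LCN2+/+ replicate 1 or LCN2-/- replicate 1 (adjusted p = 0.0581 and 0.0805, same test). Of 15 genes of MHC class I presentation, the peptidase ERAP1 (0.35, SE 0.08) and TAPBP, which bridges peptide transporter and class I molecule (0.39, SE 0.09), rose, and HLA-A (0.24, SE 0.07) and HLA-B (0.32, SE 0.10) did not pass. ERAP1 missed the test without LCN2+/+ replicate 1 (0.107) or 2 (0.0522) or LCN2-/- replicate 2 (0.0761), and TAPBP without LCN2+/+ replicate 2 (0.1) or LCN2-/- replicate 1 (0.0577). Neither list passed camera, with adjusted p of 0.972 and 0.228, and without LCN2+/+ replicate 2 that of the MHC class I list was 0.0409. Adjusted over the list alone, the counts were 2 higher and 2 lower for the interferon list and 2 higher for the MHC class I list.

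Iron handling genes, on which lipocalin 2 bears through its siderophore ligands, were mostly higher where they changed. Of 24 tested, 6 rose, 1 fell and 17 did not pass. The iron importer SLC11A2 rose by 0.82 (SE 0.06, n = 2 per genotype), the iron-responsive ACO1 by 0.84 (SE 0.07), the ferroxidase CP by 1.05 (SE 0.09) and the ferritin light chain FTL by 0.83 (SE 0.08). FTL went from 462 ± 12.3 to 790 ± 64.7 CPM. The ferritin heavy chain FTH1 (0.40, SE 0.07) and the transporter SLC39A8 (0.58, SE 0.06) rose, and LRP2, the endocytic receptor megalin, fell by 2.10 (SE 0.52) from a level of 0.453 ± 0.00769 CPM, all 3 picked out after their values were seen. Without LCN2+/+ replicate 1, FTH1 and LRP2 missed the test (adjusted p = 0.0658 and 0.0953, edgeR with Benjamini-Hochberg adjustment), and LRP2 also missed it without LCN2+/+ replicate 2 (0.0826) or LCN2-/- replicate 1 (0.121). TFRC, the transferrin receptor, was at 0.02 (SE 0.09) and HMOX1, heme oxygenase, at -0.05 (SE 0.12), neither past the test. The list as a whole did not pass camera (adjusted p = 0.101), though it did without LCN2+/+ replicate 1 (0.00984) or LCN2-/- replicate 2 (0.0347), and the counts adjusted over the list alone were 7 higher and 1 lower. Of the 6 rises, 5 passed in all 4 fits with 1 library left out.

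**Figure D3:**
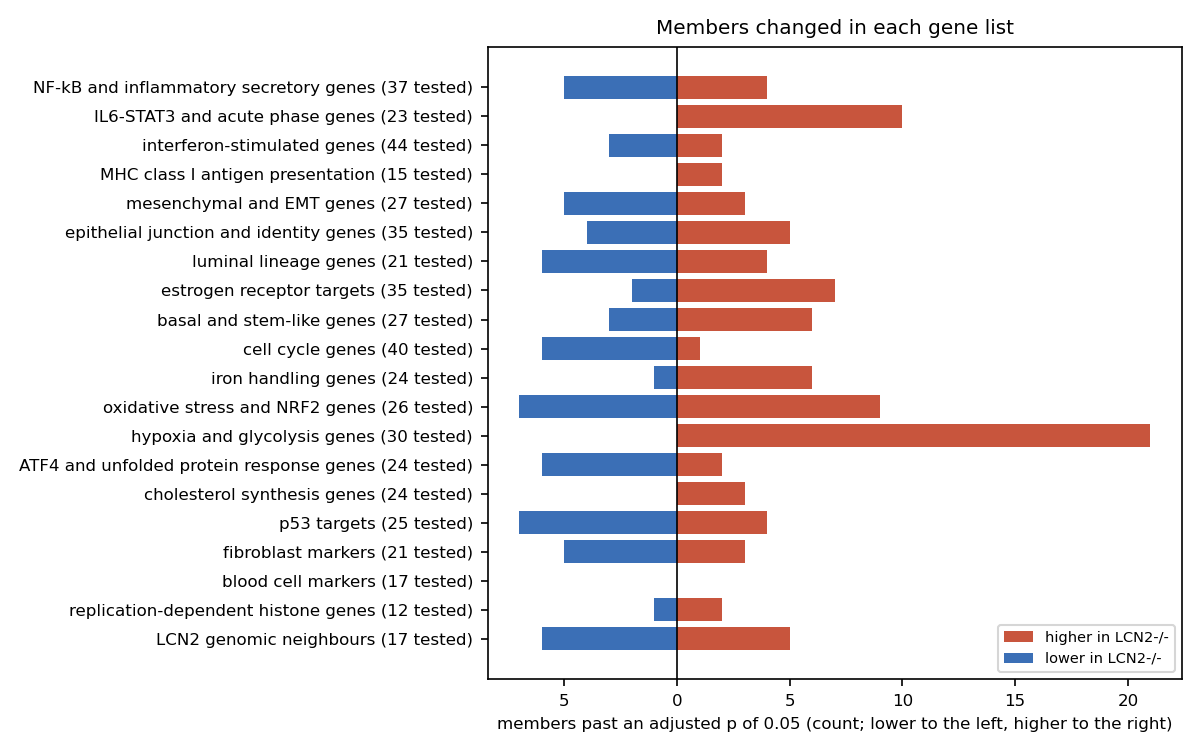
Members of 20 gene lists past an adjusted p of 0.05 (bars, counts of genes), higher in LCN2-/- cells to the right in red and lower to the left in blue, with the number tested in brackets. The hypoxia and glycolysis list reaches 21 higher and 0 lower, the IL6-STAT3 and acute phase list 10 and 0, and the oxidative stress list 9 and 7.

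Lineage genes of the mammary epithelium shifted in both directions. Of 21 luminal genes tested 4 rose and 6 fell. TFAP2A rose by 1.20 (SE 0.09, n = 2 per genotype) and the prolactin receptor PRLR by 0.64 (SE 0.07), while the trefoil peptide TFF3 fell by 1.33 (SE 0.15) and the transcription factor SPDEF by 0.45 (SE 0.06). ESR1, the estrogen receptor (0.13, SE 0.07), and FOXA1 (0.04, SE 0.07) did not pass. Of 27 basal and stem-like genes 6 rose and 3 fell, with P-cadherin CDH3 (0.83, SE 0.07), the integrin ITGB4 (1.01, SE 0.11) and SOX9 (0.80, SE 0.12) higher and the basal keratin KRT17 lower (-2.64, SE 0.18). In all 4 fits with 1 library left out, 2 of the rises and 3 of the falls of the luminal list and 4 of the rises and 1 of the falls of the basal list passed. Neither list passed camera, with an adjusted p of 0.972 for the luminal and 0.697 for the basal list, and the counts adjusted over the list alone were the same.

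Among 35 tested estrogen receptor targets 7 rose, 2 fell and 26 did not pass, a share of changed genes near the 4611 of 18180 over all tested genes. The carbonic anhydrase CA12 rose by 1.22 (SE 0.10), the fatty acid elongase ELOVL2 by 1.17 (SE 0.12) and STC2 by 1.55 (SE 0.19), the last from 251 ± 42.3 to 705 ± 148 CPM. OLFM1, on the long arm of chromosome 9, fell by 1.29 (SE 0.08) among neighbours with a median of -0.41. GREB1 (2.29, SE 1.16), TFF1 (-1.10, SE 0.55), AREG (-0.90, SE 0.55) and IGFBP4 (0.75, SE 0.38), all known targets of the receptor, did not pass. GREB1 varied widely within a genotype, at 73.4 ± 77.0 CPM in LCN2-/- cells, but was higher in LCN2-/- cells within each replicate number. It was at 128 against 26.1 CPM in replicate 1 and at 19 against 5.32 CPM in replicate 2. Within each number IGFBP4 was also higher, and TFF1 and AREG were lower. With the replicate number as a block GREB1 passed the test, and the list had a camera adjusted p of 0.00706, against 0.118 without it. What the replicate numbers mark is not stated. The list had a camera adjusted p of 0.118, which was 0.00209 without LCN2+/+ replicate 1 and 2.1e-05 without LCN2-/- replicate 2, with 7 higher and 2 lower adjusted over the list alone. Of these calls 3 rises and 1 fall passed in all 4 fits with 1 library left out.

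Genes of epithelial junctions and of the mesenchymal programme did not move as groups. Of 35 epithelial genes 5 rose and 4 fell, with E-cadherin CDH1 (0.72, SE 0.12), desmoplakin DSP (0.45, SE 0.07) and the splicing regulator ESRP2 (0.45, SE 0.07) higher and OVOL2 lower, from a level of 4.16 ± 0.447 CPM. CDH1 went from 742 ± 77.0 to 1176 ± 130 CPM (n = 2). Of 27 mesenchymal genes 3 rose and 5 fell, with WNT5A higher (0.90, SE 0.09) and the proteases MMP9 (-0.82, SE 0.16) and PLAU (-0.94, SE 0.18) and vimentin, VIM (-0.41, SE 0.08), lower. PLAU missed the test without either LCN2-/- library (adjusted p = 0.0597 and 0.0502, edgeR with Benjamini-Hochberg adjustment), and VIM missed it without LCN2+/+ replicate 1 (0.0594) or 2 (0.0678) or LCN2-/- replicate 1 (0.072). FN1, fibronectin (0.05, SE 0.20), and CD44 (-0.04, SE 0.33) did not pass. Camera gave the epithelial list an adjusted p of 0.972 and the mesenchymal list 0.477, and adjusted over the list alone the mesenchymal counts were 4 higher and 6 lower and the epithelial counts were unchanged. In all 4 fits with 1 library left out, 3 of the rises and 1 of the falls of the epithelial list and 1 of each of the mesenchymal list passed.

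Of 40 cell cycle genes 1 rose and 6 fell. MKI67, the Ki-67 antigen, rose by 1.19 (SE 0.09), from 41.6 ± 2.11 to 91.0 ± 10.7 CPM (n = 2), while the mitotic kinase PLK1 fell by 0.77 (SE 0.11), the cyclin CCNE2 by 0.55 (SE 0.11) and the helicase subunit MCM7 by 0.54 (SE 0.11). PLK1 lies in a stretch of chromosome 16 with a local median of -0.60. TOP2A (0.14, SE 0.13) and CCNB1 (-0.18, SE 0.10) did not pass. CCNE2 and MCM7 missed the test without LCN2+/+ replicate 2 (adjusted p = 0.0617 and 0.0535, edgeR with Benjamini-Hochberg adjustment). The list had a camera adjusted p of 0.101, which was 0.00313 without LCN2+/+ replicate 1 and 2.1e-05 without LCN2-/- replicate 2. Its number of lower members, also 6 when adjusted over the list alone, was 1 without LCN2+/+ replicate 2, 3 without LCN2-/- replicate 1 and 12 without LCN2-/- replicate 2, while that of higher members was 7 without LCN2-/- replicate 1. MKI67 and 1 of the 6 falls passed in all 4 such fits.

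Stress pathways showed members moving apart. In the oxidative stress and NRF2 list of 26 genes, 9 rose and 7 fell, with UGDH (1.05, SE 0.08) and OSGIN1 (0.90, SE 0.09) higher and AIFM2 (-0.82, SE 0.06) and the cystine transporter SLC7A11 (-1.39, SE 0.18) lower. UGDH lies in a stretch of chromosome 4 with a local median of 0.48. Of 24 genes of ATF4 and the unfolded protein response 2 rose and 6 fell, among them the lipoprotein receptor VLDLR (0.69, SE 0.10) upward and CHAC1 (-1.15, SE 0.15), MTHFD2 (-0.67, SE 0.09) and HERPUD1 (-0.59, SE 0.10) downward. HSPA5, the main chaperone of the endoplasmic reticulum, was at 0.29 (SE 0.12) and did not pass. Of 25 p53 targets 4 rose and 7 fell, with BTG2 (0.86, SE 0.08), TP53INP1 (0.62, SE 0.06) and SPATA18 (0.83, SE 0.12) higher, EDA2R lower (-0.90, SE 0.14), and CDKN1A (-0.22, SE 0.07) and MDM2 (-0.08, SE 0.07) not past the test. BTG2 lies among neighbours with a median of 0.52. Camera gave these lists adjusted p of 0.972, 0.307 and 0.228, and adjusted over the list alone the p53 targets had 11 lower members and the other counts were the same. In all 4 fits with 1 library left out, 3 rises and 3 falls of the oxidative stress list, 1 rise and 4 falls of the ATF4 list and 3 rises and 3 falls of the p53 list passed.

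Cholesterol synthesis genes passed the camera test with an adjusted p of 0.0289, which became 0.988 with an estimated correlation, at a median log2 fold change of 0.19. Of 24 tested, MVD (0.37, SE 0.08), LSS (0.33, SE 0.07) and STARD4 (0.80, SE 0.20) rose and 0 fell, DHCR24 (0.36, SE 0.10) and HMGCR (-0.12, SE 0.09), the enzyme that sets the pathway's rate, did not pass, and 2 rose when adjusted over the list alone. MVD lies among neighbours with a median of 0.35. The list had a camera adjusted p of 0.263 without LCN2+/+ replicate 2 and 0.293 without LCN2-/- replicate 1, and 0 of its 3 changed members passed in all 4 fits that left out 1 library. Without LCN2-/- replicate 2, 7 members rose, and in each of the other 3 fits 1 did. MVD missed the test without either LCN2+/+ library (adjusted p = 0.0531 and 0.0754, edgeR with Benjamini-Hochberg adjustment) or LCN2-/- replicate 1 (0.063), LSS without LCN2+/+ replicate 1 (0.0957) or LCN2-/- replicate 2 (0.0749), and STARD4 without either LCN2+/+ library (0.091 and 0.0687) or LCN2-/- replicate 1 (0.19). Of 12 tested histone genes H4C8 (0.79, SE 0.09) and H2BC21 (0.47, SE 0.06) rose, both also in all 4 fits with 1 library left out, and H1-2 fell (-0.51, SE 0.09; adjusted p = 0.0563 by edgeR with Benjamini-Hochberg adjustment without LCN2+/+ replicate 2), with the same counts adjusted over the list alone and a camera adjusted p of 0.972. H2BC21 lies in a stretch of chromosome 1 with a local median of 0.43.

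Of 21 tested fibroblast markers 3 rose and 5 fell, the calls including COL5A2 and TAGLN (above), FBLN1 (-2.08, SE 0.16) and COL6A1 (-0.71, SE 0.13), and the median member stood at 3.69 and 2.37 CPM in the LCN2+/+ and 1.01 and 1.22 CPM in the LCN2-/- libraries. Of 17 blood cell markers 0 rose and 0 fell by edgeR's quasi-likelihood test (6 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom; 3 rose without LCN2+/+ replicate 2, and 1 fell without each of LCN2+/+ replicate 1, LCN2+/+ replicate 2 and LCN2-/- replicate 2), and HBA1 (-1.34, SE 0.43) and LYZ (-0.52, SE 0.18) were not past it. PTPRC, a gene of white blood cells, stood at 12.6, 25.7, 19.3 and 21.1 CPM in LCN2+/+ replicates 1 and 2 and LCN2-/- replicates 1 and 2. Both lists had a camera adjusted p of 0.307, but that of the fibroblast list was 0.0472 without LCN2+/+ replicate 2 and that of the blood list 0.00984 without LCN2+/+ replicate 1. Of the fibroblast calls 0 rises and 3 falls passed in all 4 fits with 1 library left out. Adjusted over the list alone, 4 fibroblast markers rose and 5 fell, and 0 blood cell markers did either. The mitochondrially encoded genes have no entries in the tables used here.

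Of 17 tested genes beside LCN2 on chromosome 9, 5 rose and 6 fell. Of 13 neighbours on the centromeric side 5 rose and 3 fell, with the kinase CDK9 at 0.33 (SE 0.07, n = 2 per genotype) and ST6GALNAC4 at -1.45 (SE 0.20). Of 4 neighbours on the telomeric side 0 rose and 3 fell, with C9orf16 at -0.72 (SE 0.13). PTGES2, the nearest of the centromeric neighbours, fell by 0.64 (SE 0.06). CDK9 missed the test without LCN2+/+ replicate 2 or LCN2-/- replicate 1 (adjusted p = 0.0863 and 0.0599 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). All 17 neighbours together had a camera adjusted p of 0.972, with 6 higher and 6 lower adjusted over the list alone. Of their 5 rises 0, and of their 6 falls 3, passed in all 4 fits with 1 library left out.

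Over more genes, all with a mean of at least 1 CPM, the medians of both sides had opposite signs. The 30 tested genes nearest to LCN2 on the centromeric side, from position 125747345, had a median log2 fold change of 0.37, with 24 of 30 above 0. The 30 nearest on the telomeric side had a median of -0.57, with 30 of 30 below 0. From LCN2 to the end of the last tested gene, at 138177433, 108 of 152 tested genes fell and 4 rose, and their median stood at 68.4% of the LCN2+/+ level. PTGES and OLFM1 are among them. A single step fitted to the 226 tested genes from 120 Mb onward fell between NAIF1 (0.36, SE 0.09) and SLC25A25 (-0.36, SE 0.08), 80.9 kb and 3 tested genes before LCN2, with means of 0.43 before it and -0.55 after it.

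**Figure D4:**
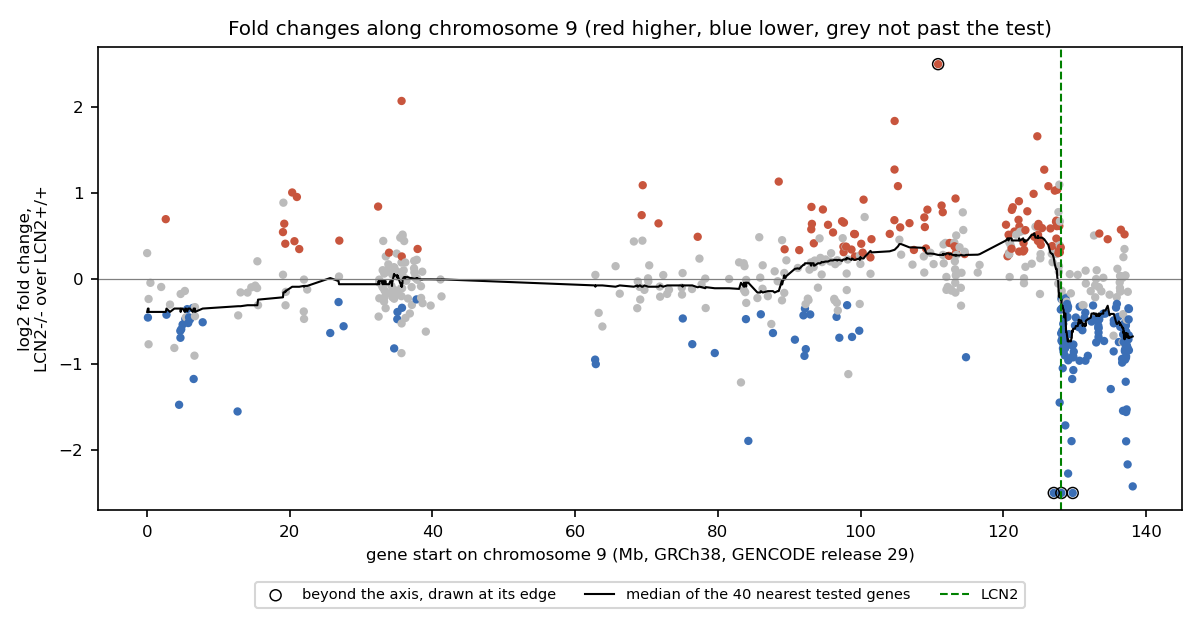
Log2 fold change (LCN2-/- over LCN2+/+, y axis) of each tested gene on chromosome 9 with a mean of at least 1 CPM against the start of the gene (x axis, Mb, GRCh38). Points are red where higher, blue where lower and grey where not past the test, and ringed points lie beyond the axis. The black line, the median of the 40 nearest tested genes, passes below 0 shortly before LCN2 (green dashed line), where it stands at -0.25, and the 30 genes on either side of LCN2 have medians of 0.37 and -0.57.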

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

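Local centring, which takes each fold change relative to that of its genomic neighbours, was the only alternative whose tests were chosen after the result was seen. LCN2 was called lower under all 15 alternatives, between -3.54 without LCN2-/- replicate 2 and -3.08 with local centring. With the replicate block, 7869 genes changed, 3853 higher and 4016 lower, and 4600 of the 4611 calls were kept. The labels do not say what the replicate numbers mark, there are only 2 such pairs, and the deviations of like-numbered libraries from their genotype means correlated across genes at 0.191 (0.583 among genes with a mean of at least 5 CPM), genes not being independent replicates. In that fit 955 genes were higher in replicate 1 and 286 in replicate 2, GREB1 and IGFBP4 among the former. GREB1 was at 128 against 26.1 CPM in LCN2-/- and LCN2+/+ replicate 1 and at 19 against 5.32 CPM in replicate 2, and with the block it passed the test (2.19, adjusted p = 0.000484). The block gave estrogen receptor targets and cell cycle genes each a camera adjusted p of 0.00706. With 1 library left out, between 3021 and 3542 genes changed, between 1472 and 1763 of them higher and between 1549 and 1813 lower, the lowest counts being those without LCN2+/+ replicate 1. With a mean of at least 5 CPM, 347 genes changed at least 2-fold, where 10627 genes were tested. The other counts of changed genes lay within 1.5 times of 4611, between 3296 with local centring and 6231 with no low-count filter, and the share of higher genes was between 47.9% and 49.8% under every alternative.

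With local centring 2784 of the 4611 calls (60.4%) were kept, 12 of them with the opposite sign. Among named genes it ended 16 calls. The fold changes of PLK1 (-0.77 to -0.17), MCM7 (-0.54 to -0.24), MVD (0.37 to 0.03), H2BC21 (0.47 to 0.05), C9orf16 (-0.72 to -0.48) and ENO1 (0.92 to 0.37) shrank as the neighbours' median was taken off, while STARD4 kept most of its own (0.80 to 0.76, adjusted p = 0.0517). It raised ESR1 to 0.50, past the test, and gave the MHC class I list a camera adjusted p of 0.01, estrogen receptor targets 0.0215 and cholesterol synthesis 0.0965. The hypoxia and glycolysis list passed camera under all alternatives in which it was run, with adjusted p between 2.86e-12 and 2.77e-06 at the preset correlation, but had adjusted p = 0.904 with an estimated correlation and 0.109 by fry in the fit of all 4 libraries. Cholesterol synthesis had 0.118 with a mean of at least 5 CPM, and estrogen receptor targets, cell cycle and iron handling genes each had 0.0266 with no low-count filter. Over all alternatives camera adjusted p ran from 5.08e-05 to 0.0691 for IL6-STAT3, 0.000237 to 0.293 for cholesterol synthesis, 2.1e-05 to 0.677 for estrogen receptor targets, 2.1e-05 to 0.909 for cell cycle, 0.00984 to 0.287 for iron handling and 0.01 to 0.683 for MHC class I genes. The range was 0.0472 to 0.94 for fibroblast and 0.00984 to 0.849 for blood cell markers, 0.0115 to 0.17 for complement, 0.000647 to 0.673 for S100, 0.0169 to 0.741 for mucin and 0.0074 to 0.274 for actin-binding genes.

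Hepatocyte transcripts turned with the LCN2+/+ library that was kept. ALB was at -1.09 without LCN2+/+ replicate 2 and at 1.17 without replicate 1, and FGA at -1.11 and 1.41. The camera adjusted p of the hepatocyte markers, with 1 library left out, lay between 5.06e-05 without LCN2+/+ replicate 2 and 0.767 without LCN2-/- replicate 2, and was 0.000504 without LCN2+/+ replicate 1, in the other direction. With 1 library left out, that of the held-out hepatocyte markers lay between 9.73e-05 without LCN2+/+ replicate 2 and 0.821 without LCN2-/- replicate 1, and was 0.0240 without LCN2+/+ replicate 1, in the other direction. Except where a value above gives it, the cause was not tested. Over all named genes and alternatives, 2669 comparisons kept their direction and side of the threshold, 118 were no longer past it, 87 were newly past it and 2 turned. For list tests these numbers were 339, 9, 41 and 2. In simulated counts with the same number of libraries, 61.3% of genes changed 1.5-fold were recovered. Far fewer genes were changed there than were called in the data, so this rate need not hold in the data.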

Other observations

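The lists of complement, S100, mucin and actin-binding genes, and the tests of coincidence, DNA loss, unrelated copy number differences, admixture, scaling and genotype below, were chosen after the result was seen. Camera values of these lists therefore describe the same data that prompted them and are no independent support. Several genes of the complement cascade were higher in LCN2-/- cells. Beside C3, the proteases C1R and C1S that start the classical pathway rose by 1.5 (SE 0.11, n = 2 per genotype) and 1.47 (SE 0.10) on the log2 scale, as did CFB (1.30, SE 0.10) and the membrane inhibitor CD59 (0.58, SE 0.11). Of 21 tested complement genes 5 rose, 0 fell and 16 did not pass by edgeR's quasi-likelihood test, and 4 of the 5 passed in all 4 fits with 1 library left out, CD59 having an adjusted p of 0.0512 without LCN2+/+ replicate 2. The list had a camera adjusted p of 0.0756 over the 8 added lists, under 0.05 without LCN2+/+ replicate 1 (0.0259) or either LCN2-/- library (0.0115 and 0.0433), and adjusted p = 0.849 with an estimated correlation. Of 15 S100 genes 5 rose and 1 fell. S100A9 and S100A8, the subunits of calprotectin, rose by 1.13 (SE 0.10) and 0.84 (SE 0.10), S100A9 from 1250 ± 160 to 2619 ± 147 CPM, and S100A7 by 0.98 (SE 0.08), while S100A16 fell by 1.93 (SE 0.11). S100A4 (adjusted p = 0.0502 and 0.0848 without LCN2+/+ replicate 1 or 2) and S100A11 (0.0722 without LCN2+/+ replicate 2) also rose, and 3 of the 5 rises and the fall passed in all 4 fits with 1 library left out. The S100 list had a camera adjusted p of 0.0336, which was 0.0732 without LCN2-/- replicate 1, 0.673 with local centring and adjusted p = 0.849 with an estimated correlation, and its members had a median local median of 0.28.

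Mucin genes and actin-binding genes changed in both directions. MUC15 fell by 5.86 (SE 0.46) and the gel-forming mucin MUC5AC by 2.59 (SE 0.25), while MUC1 rose by 0.82 (SE 0.14), the only 3 changes among 8 tested mucins, each of which passed in all 4 fits with 1 library left out, with a camera adjusted p of 0.0756. The camera value of the mucin list moved with the library that was left out. REG4, a secreted lectin, fell by 6.0 (SE 0.20), and the imprinted RNA H19 fell by 2.41 (SE 0.08). Of 26 actin-binding and contractile genes 3 rose and 7 fell. Beside PLS3, LCP1 and TAGLN, the smooth muscle actin ACTG2 fell by 2.66 (SE 0.16) and the tropomyosin TPM4 by 0.94 (SE 0.08). LCP1 lay among neighbours with a local median of -0.37. The severing proteins SCIN and GSN rose by 2.23 (SE 0.20) and 0.80 (SE 0.08), GSN among neighbours with a local median of 0.44. Of these calls 2 rises and 6 falls passed in all 4 fits with 1 library left out. The list had a camera adjusted p of 0.0756, under 0.05 without LCN2+/+ replicate 2 (0.0074) or either LCN2-/- library (0.012 and 0.0433), and both it and the mucin list had adjusted p = 0.849 with an estimated correlation.

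Fold changes on the long arm of chromosome 9 turned from higher to lower near LCN2, with medians of 0.37 and -0.57 over the 30 genes on either side and a best single step 80.9 kb before LCN2. The contrast of 0.94 (bootstrap SE 0.15) was reached at 0 of 12130 positions more than 30 genes away, and 77 lay above 0.640, the contrast less 2 SE. Contrasts of this size were thus rare. The largest other one, 0.903 at FXYD3 on chromosome 19, was nonetheless closer to that at LCN2 than the SE. Neighbouring positions also share genes, so the scan cannot decide whether the boundary falls here by coincidence. After the trend on GC content and transcript length was removed, the contrast at LCN2 stood at 0.963 (SE 0.126), which argues against such bias. Loss of DNA telomeric to LCN2 is a candidate explanation for the lower side, where 88.2% of the 152 telomeric genes were below 0. That share restates the pattern and would follow from any cause that lowers the region, so it does not single out DNA loss. The largest contrast on the chromosome, 1.06, stood at FPGS, 12 genes away. A loss of telomeric DNA would leave the rise on the centromeric side unexplained. For the rise and for the fall, copy number differences between the cell lines unrelated to the edit cannot be told apart from the genotype. Outside chromosome 9, 860 genes also had a local median beyond 0.35 in either direction, and the labels give both libraries of a genotype 1 code. Such stretches had medians of 0.48 over 184 genes on chromosome 1, -0.55 over 183 on chromosome 16 and -0.67 over 64 on chromosome 19.

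LCN2 transcript stayed detectable in both LCN2-/- libraries, at 9.98% of the LCN2+/+ level. Mixing of LCN2+/+ cells or reads into these libraries at that share is argued against by 7 genes with a lower share and separate 95% limits, among them CT83 at 0.590% and PLS3 at 1.27%. Loss of telomeric DNA as the whole cause of the fall is argued against by the median telomeric gene, at 68.4% of its LCN2+/+ level. Transcripts of the edited alleles may account for the rest, which cannot be told apart from other sources here because counts per gene hold no sequence.

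Most T lymphocyte markers were lowest in LCN2+/+ replicate 1, with CD3E at 1.87 CPM there against 6.29 in LCN2+/+ replicate 2 and 5.31 and 5.79 in the LCN2-/- libraries, but the held-out marker RHOH was lowest in the LCN2-/- libraries (1.69 and 1.59 against 2.19 and 2.74 CPM) and the B lymphocyte marker CD79A was highest in LCN2+/+ replicate 1 (2.97 CPM). T lymphocyte RNA or reads in the other libraries are a candidate source, since 100% of 20 held-out T lymphocyte markers were lower there than in LCN2+/+ replicate 2 (markers shared with another list were dropped from this set after the result was seen). Scaling or depth is argued against by held-out hepatocyte markers, at a median log2 ratio of 1.37 the other way, with ALB at 125 against 26.4 CPM. The LCN2 genotype is argued against by the held-out T lymphocyte markers as a set, whose median log2 ratio of LCN2-/- libraries over LCN2+/+ replicate 2 was -0.18. This rests on 1 LCN2+/+ library, and the first T lymphocyte list had already given 0.04. It does not hold for EOMES, at 5.36 and 5.76 CPM in the LCN2-/- libraries against 1.78 and 2.30 CPM in LCN2+/+ replicates 1 and 2. What brought either set of transcripts into the libraries stays open, PTPRC at 12.6 to 25.7 CPM being the most abundant of the lymphocyte genes looked at.

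The T lymphocyte markers, of which CD3D and CD3E are also in the blood cell list, had 0 of 20 members changed by edgeR's quasi-likelihood test (0 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom). Their camera adjusted p was 0.0190, 0.849 with an estimated correlation and 0.495 without LCN2+/+ replicate 1. Without LCN2+/+ replicate 2, 19 of the 20 were called higher. Of the held-out T lymphocyte markers 1 of 20 rose, EOMES at 1.51 (SE 0.18), and 10 rose without LCN2+/+ replicate 2. This list had a camera adjusted p of 0.0756, which was 1.42e-06 without that library and 0.0247 without LCN2-/- replicate 2. The hepatocyte markers, 3 of them (FGA, FGB and FGG) also in the IL6-STAT3 list, had 0 of 9 changed and a camera adjusted p of 0.994, and their held-out markers 0 of 14 and 0.897, with 0 of either at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. Without LCN2+/+ replicate 1, 5 hepatocyte and 3 held-out markers were called higher, and without LCN2+/+ replicate 2, 7 and 6 were called lower. Fibroblast markers were higher in LCN2+/+ replicate 1 than in replicate 2 for 20 of 21, by a median log2 ratio of 0.44.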
